A study of Homo sapiens with 6 samples.

How the data were processed

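RNA from primary human keratinocytes was sequenced in 6 libraries, 3 after vehicle and 3 after mevastatin. Per the labels' protocols, cells were grown to about 90% confluency and held in basal medium for 5 h, mevastatin was given at 5 µM 3 times daily every 4 h over 48 h, and libraries followed standard Illumina protocols. Groups and replicate numbers were taken from the labels. Other details of the labels about the cells' source are not used here.

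The authors' deposited table holds raw read counts per gene, per the file headers, for 57820 genes with hg19 coordinates. Base calls were made with bcl2fastq 2.17 and reads aligned with STAR 2.5.0a to hg19/GRCh37, per the submitters' processing notes. The counting tool, its strand setting and the annotation release are not given in the sources used here. Coordinates in the text are those of the table and span whole genes. Reads shared by overlapping genes, antisense pairs, paralogs or pseudogenes may therefore have been assigned to either or to none. Genes named by the rule whose spans overlap another expressed gene are marked where the Results describe them. Overlaps of other genes were not examined. The table also holds CPM values that the authors normalised, per the file headers. In the deposited CPM each library was divided by a single factor, which is 2.41 to 2.45 times the effective library size computed here from the counts, so that a column sums to between 402526 and 417857. Deposited CPM were not used for any value in the report, and CPM in the text were computed from the counts. The same table gives the authors' log2 fold changes with their p-values and FDR from edgeR, adjusted p-values from DESeq and FDR from baySeq, per the file headers, which are quoted as the authors' own. A second table, lists of gene identifiers by tool, was not used here.

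In 1 row the counts were replaced by a letter, and that gene was not analysed. Genes of chromosome Y, *XIST* and *TSIX* (544 rows) were removed before any step, which left 57275 genes. Counts on the mitochondrial genome were 0 in each library. Total counts ranged from 27347302 to 50460024 per library, which sets the precision of low values. In all pairs of replicates the chi-square of the counts exceeded its degrees of freedom 8.98-fold or more, so no library was a repeat sequencing of another. This does not tell separate cultures from separate library preparations of 1 culture. Intervals on ratios of few counts are exact conditional binomial intervals at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.

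Genes were filtered with filterByExpr of edgeR 4.0.16, which kept 18775, scaled by TMM (factors 0.978 to 1.02) and tested with the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) with treatment as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The common biological coefficient of variation was 9.03%. Standard errors of log2 fold changes were derived from the test's F statistic. CPM are given as mean ± SD over the 3 libraries of a group. In R 4.3.3, limma 3.58.1 gave the gene list tests: 39 lists were written from textbook knowledge before the data were examined, and the 34 with at least 4 tested members were tested with camera, two-sided, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and adjusted over the 34. The count of changed members is given over all genes tested and adjusted over the list alone. With an estimated correlation, 0 of the 19 calls held (lowest adjusted p 0.0842; 23 lists were called by fry, limma's rotation test), and at an unadjusted p under 0.05 the changed-gene test had 6855 genes.

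The genes named in the text were fixed by a rule written before the data were examined: *CAV1*, *EGFR*, *MYC*, *GAS5*, *NR3C1* and *RHOB* always, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 CPM and no overlap between groups, without clone names or pseudogenes, and up to 4 members with the smallest p in each described list. Members outside this rule that identify a small count are said to have been named after their values were seen. Some genes that the rule names and 1 of the tested lists are not reported here.

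The test was checked on simulated counts with the means and library sizes of the 18775 genes of this comparison, in 5 sets with 200 changed genes each. With the dispersion of each gene, it recovered 60.6% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 94.2% of those changed 4-fold, and 10.5% of its calls were unchanged genes (4.26% with dispersions on the trend). A simulated list of 20 genes raised 1.5-fold was called by camera (adjusted p = 7.99e-34) and with an estimated correlation (adjusted p = 0.0168). Of 100 unchanged lists, 0 were called by camera. Genes were simulated independently of each other, so these checks do not cover lists of correlated genes. In the data, the estimated correlation of a called list reached 0.53 (targets of ATF4).

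Alternatives set before the data were examined were median-of-ratios scaling, library totals alone, no count filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a 2-fold minimum, fry, and camera with an estimated correlation. The gene families of the closing section were chosen after the data had been examined.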

Results

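Gene expression was measured by RNA sequencing in primary human keratinocytes, the epithelial cells of the epidermis grown in culture from skin. Cells were given mevastatin, a statin, which is a drug that inhibits the mevalonate pathway, or vehicle. Each group held 3 libraries, numbered 1 to 3. Mevastatin was given at 5 µM, 3 times a day every 4 h, and cells were collected for the 48 h sample. The vehicle libraries held 27347302, 50460024 and 33763004 counts and the mevastatin libraries 39202830, 47816019 and 36278188 counts. The 20 most abundant genes took between 13.6% and 14.6% of the counts in each library. The labels do not say whether the replicates of a group came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical. The study's title concerns caveolin-1 and EGF receptor signalling in healing, and the comparison of mevastatin with vehicle addresses which transcripts differ with the drug.

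With mevastatin, genes of cholesterol and fatty acid synthesis rose together, while genes of DNA replication and mitosis and interferon-stimulated genes fell. The median gene of the mevalonate and cholesterol pathway was 2.84-fold higher. The median gene of mitosis was 12.6-fold lower, and the median interferon-stimulated gene was 2.73-fold lower. *CAV1* and *EGFR*, the genes of caveolin-1 and of the EGF receptor, did not pass the threshold. In all, 4927 of 18775 tested genes (26.2%) differed between the groups at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 2432 higher and 2495 lower with mevastatin. Of these, 331 were higher and 495 lower by at least 2-fold. Scaled by library totals alone, the split was 1996 higher and 3115 lower, so that 39.1% of changed genes were higher in place of 49.4%. The first principal component held 57.1% of the variance and separated the groups.

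Nearly the whole mevalonate and cholesterol pathway was higher with mevastatin. Of 21 tested enzymes, 19 rose and none fell, over all genes tested and adjusted over the list alone. The median log2 fold change of the list was 1.51 (camera, adjusted p = 5.82e-21; adjusted p = 0.0842 with an estimated correlation). *MVD*, the mevalonate diphosphate decarboxylase (ENSG00000167508.6, chromosome 16, 88718343 to 88729569, reverse strand, hg19), rose 7.10-fold, from 18.7 ± 1.34 CPM to 133 ± 8.01 CPM (SD, n = 3 each; log2 fold change 2.83 ± 0.076 SE; adjusted p = 1.24e-14). *HMGCS1*, an enzyme of the early pathway, rose 4.91-fold to 1808 ± 121 CPM (SD, n = 3). *MSMO1*, a later demethylating enzyme of the pathway, rose 3.61-fold. *ACAT2*, which makes acetoacetyl-CoA, rose 5.03-fold, but its span overlaps *TCP1* and *SOD2*, and reads of overlapping genes may have been split between them. The 2 members that were not called, named here after their values were seen, were *PMVK* (log2 fold change 0.07 ± 0.14 SE) and *GGPS1* (-0.03 ± 0.066 SE), whose enzyme makes geranylgeranyl diphosphate.

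Genes of sterol uptake and of SREBP2 feedback rose as well. Of 11 tested members, 10 were higher and none lower, also adjusted over the list alone, with a median log2 fold change of 1.09 (camera, adjusted p = 3.53e-09; adjusted p = 0.0842 with an estimated correlation). *INSIG1*, which holds SREBP proteins in the endoplasmic reticulum (ENSG00000186480.8, chromosome 7, 155089486 to 155101945, forward strand), rose 4.29-fold, from 79.3 ± 1.62 CPM to 340.0 ± 15.4 CPM (SD, n = 3 each; log2 fold change 2.10 ± 0.062 SE; adjusted p = 2.85e-14). *LPIN1* rose 3.36-fold, and *TMEM97*, whose span overlaps *IFT20*, rose 4.38-fold. The member not called was *SCAP* (log2 fold change -0.09 ± 0.082 SE), named after its value was seen.

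Fatty acid synthesis and desaturation followed. Of 15 tested genes, 14 were higher and none lower (15 higher adjusted over the list alone), with a median log2 fold change of 0.63 (camera, adjusted p = 2.12e-12; adjusted p = 0.0842 with an estimated correlation). *SCD*, the stearoyl-CoA desaturase, rose 4.36-fold, from 667 ± 45.2 CPM to 2907 ± 119 CPM (SD, n = 3 each). *ACSS2*, which makes acetyl-CoA from acetate, rose 6.13-fold. *ACLY*, the ATP citrate lyase, rose 3.07-fold. *FADS2*, a fatty acid desaturase, rose 7.25-fold, and its span overlaps *FADS1* and *FEN1*. *ACACB*, named after its value was seen, was not called over all genes (log2 fold change 0.63 ± 0.26 SE; adjusted p = 0.0809).

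Targets of the liver X receptors, which sense oxysterols, moved in both directions. Of 12 tested members, 4 were higher and 4 lower, also adjusted over the list alone, and the list as a whole was not called (median log2 fold change -0.14; camera, adjusted p = 0.435). *ABCA1*, a cholesterol exporter, fell 2.39-fold, from 165 ± 8.64 CPM to 69.0 ± 3.67 CPM (SD, n = 3 each; adjusted p = 5.19e-11). *ABCG1*, another sterol exporter, was 3.21-fold lower, and *MYLIP*, which encodes a ubiquitin ligase, was 2.32-fold lower. *APOE* was 1.32-fold higher. The other lower member was *PLTP*, and the other higher members were *SREBF1*, *APOC1* and *NR1H2*, all named after their values were seen. By fry this list was called (adjusted p = 0.00185).

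The cell cycle showed the largest shift among the 34 tested lists. All 34 genes of G2 and mitosis were lower with mevastatin, also adjusted over the list alone, with a median log2 fold change of -3.66 (camera, adjusted p = 6.56e-30; adjusted p = 0.0842 with an estimated correlation). *TOP2A*, the topoisomerase of dividing cells (ENSG00000131747.10, chromosome 17, 38544768 to 38574202, reverse strand), fell 32.1-fold, from 60.5 ± 7.97 CPM to 1.87 ± 0.230 CPM (SD, n = 3 each; log2 fold change -5.01 ± 0.12 SE; adjusted p = 6.56e-15). *DLGAP5* was 53.2-fold lower, *BUB1*, a kinase of the spindle checkpoint, 12.1-fold lower, and *NUSAP1* 7.54-fold lower. Of 32 genes of DNA replication and the G1/S transition, 29 were lower and none higher (30 lower adjusted over the list alone), with a median log2 fold change of -1.5 (camera, adjusted p = 9.15e-22; adjusted p = 0.0842 with an estimated correlation). *RRM2*, a ribonucleotide reductase subunit, fell from 8.59 ± 0.276 CPM to 0.125 ± 0.0755 CPM (SD, n = 3 each). *EXO1* was 20.3-fold lower, *CLSPN* 10.2-fold lower and *CDC6*, a replication licensing factor, 7.27-fold lower. Those not called, named after their values were seen, were *RFC2* (log2 fold change -0.33 ± 0.12 SE), *UNG* (-0.11 ± 0.081 SE) and *SLBP* (0.08 ± 0.066 SE). Most mitosis genes were near or under 1 CPM with mevastatin, so the size of their fall is less certain than its direction.

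The 12 largest decreases were *HIST1H3G*, *NEK2*, *RRM2*, *CENPA*, *SKA1*, *DLGAP5*, *AURKB*, *HJURP*, *KIF20A*, *HIST1H3B*, *BIRC5* and *FAM111B*. *HIST1H3G* had 317 counts over the vehicle libraries and 2 over the mevastatin libraries, a ratio of 170 with a 95% exact interval of 46.6 to 1408 that covers counting error only. The others were between 40.1-fold (*FAM111B*) and 64.6-fold lower (*NEK2*). With one mevastatin library left out, the fold change of 6 of these others moved by more than 1.5-fold. The log2 fold change was -6.74 for *AURKB*, -4.66 for *BIRC5*, -6.09 for *HIST1H3B*, -6.67 for *RRM2* and -5.20 for *SKA1* without replicate 2, -7.03 for *SKA1* and -6.60 for *NEK2* without replicate 1, and -6.19 for *BIRC5* without replicate 3. Both mevastatin counts of *HIST1H3G* were in replicate 1. The spans of *CENPA* and *KIF20A* overlap other expressed genes. Of 12 tested genes in the list of replication-dependent histones, 4 were lower and none higher, also adjusted over the list alone, and the list was not called (camera, adjusted p = 0.0521). *HIST1H3B* and *HIST1H1B* were 42.6-fold and 8.02-fold lower, and *HIST1H2BK* was lower with a call that ended without mevastatin replicate 2 (adjusted p = 0.0635) or vehicle replicate 3 (0.0621). The list was called with no count filter (adjusted p = 0.010), by fry (0.0286) and without mevastatin replicate 2 (0.0496), mevastatin replicate 3 (0.0187) or vehicle replicate 1 (0.0140). Histone genes have near-identical copies, so counts of single members are uncertain. The call of *HIST1H1D* (3.04-fold lower; adjusted p = 0.0375) ended with no count filter (0.0835) and with any one library left out, at an adjusted p between 0.0507 and 0.118.

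**Figure D1:**
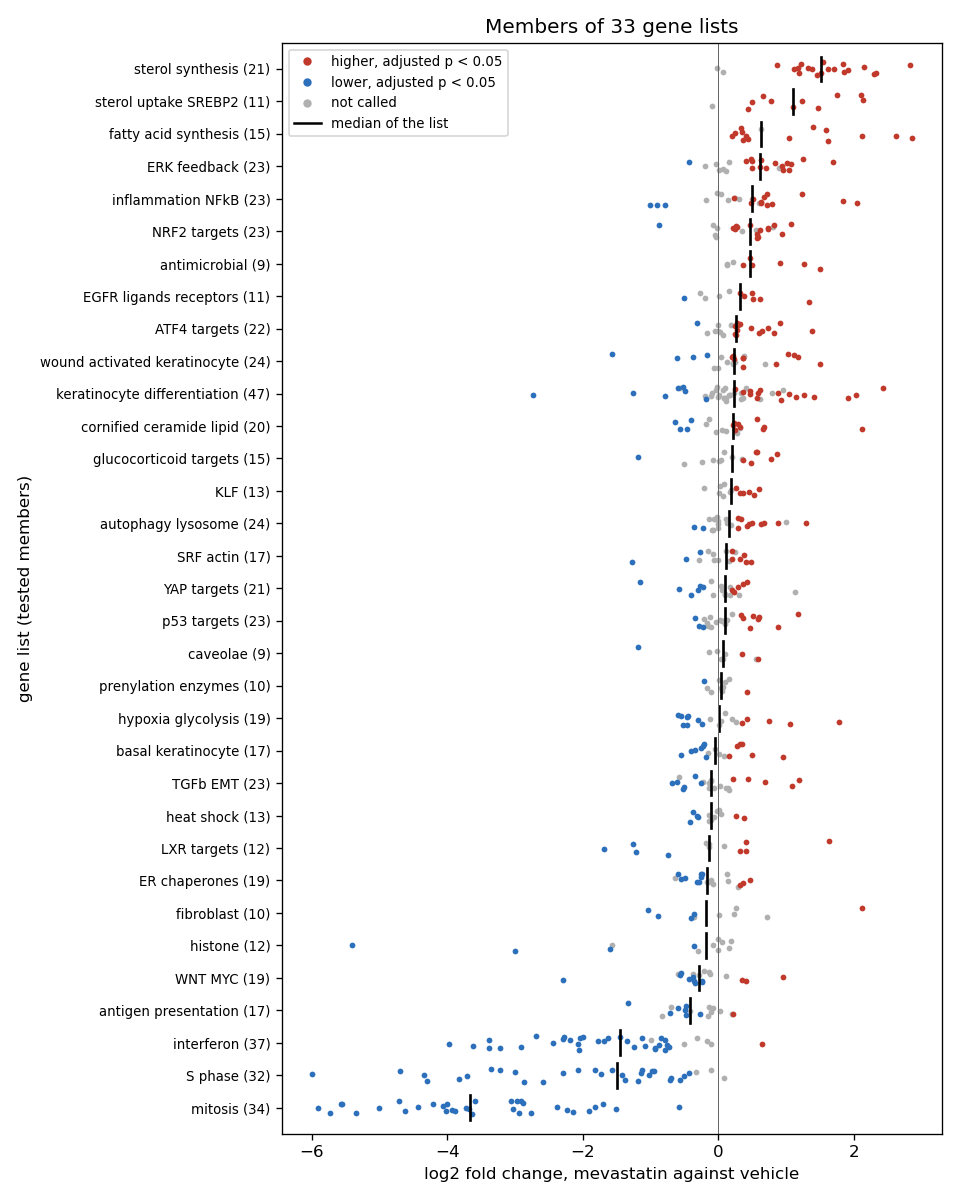
Log2 fold change of each tested member of 33 gene lists, mevastatin against vehicle (horizontal axis), with lists ordered by their median and the number of tested members in brackets. Points are genes, coloured where the adjusted p was under 0.05, and black bars are medians: the medians of sterol synthesis (1.51) and mitosis (-3.66) lie at the ends of the order.

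Interferon-stimulated genes were lower with mevastatin. Of 37 tested members, 31 were lower and 1 higher (32 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -1.45 (camera, adjusted p = 1.59e-22; adjusted p = 0.112 with an estimated correlation). *OAS2*, an antiviral oligoadenylate synthetase (ENSG00000111335.8, chromosome 12, 113416200 to 113449528, forward strand), fell 7.5-fold, from 48.9 ± 4.76 CPM to 6.52 ± 0.129 CPM (SD, n = 3 each; log2 fold change -2.91 ± 0.095 SE; adjusted p = 1.06e-13). *ISG15*, a ubiquitin-like protein, was 6.43-fold lower and *IFI27* fell 4.12-fold, from 201 ± 17.5 CPM to 48.7 ± 3.74 CPM (SD, n = 3 each). The higher member was *ISG20* (log2 fold change 0.64 ± 0.17 SE). The members not called were *IRF9* (-0.50 ± 0.19 SE), *IFIT2* (-0.99 ± 0.82 SE), *OASL* (-0.17 ± 0.20 SE), *IRF1* (-0.10 ± 0.17 SE) and *RSAD2* (-0.32 ± 0.92 SE). These 6 were named after their values were seen. Antigen presentation was lower too, with 7 of 17 tested members lower and 1, *HLA-E*, higher (8 lower and 1 higher adjusted over the list alone; camera, adjusted p = 0.00272; adjusted p = 0.115 with an estimated correlation). *B2M*, the light chain of HLA class I, fell 1.39-fold from 1117 ± 21.8 CPM (SD, n = 3). *PSMB8* was 1.65-fold lower, *TAP2* 1.40-fold lower and *HLA-B*, whose reads may be shared with other HLA class I genes, 1.52-fold lower. Without vehicle replicate 3 the median log2 fold change of that list was -0.23, against -0.42 with all libraries. *HLA-E* was named after its value was seen.

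*CAV1* (ENSG00000105974.7, chromosome 7, 116164839 to 116201233, forward strand) stood at 1038 ± 24.5 CPM with vehicle and at 940 ± 6.79 CPM with mevastatin (SD, n = 3 each). Its log2 fold change of -0.14 ± 0.054 SE had an adjusted p of 0.0565. It was called with library totals alone (adjusted p = 0.0130), with limma-voom (0.0312) and with a mean count of at least 50 (0.0472). Among 9 tested genes of caveolins, cavins and associated proteins, 2 were higher and 1 lower (2 and 2 adjusted over the list alone), with *CAV1* past the threshold over the list alone (adjusted p = 0.0348), and the list was not called (median log2 fold change 0.06; camera, adjusted p = 0.50). The higher ones were *PACSIN3* (1.27-fold) and *PRKCDBP* (1.51-fold), and the lower one was *SDPR* (2.27-fold; adjusted p = 0.0487), which was no longer called in DESeq2 (adjusted p = 0.0815), a call that also ended without each library but vehicle replicate 1, at an adjusted p of 0.0550 to 0.297.

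*EGFR* (ENSG00000146648.11, chromosome 7, 55086714 to 55324313, forward strand) stood at 567 ± 32.3 CPM with vehicle and at 634 ± 48.7 CPM with mevastatin (SD, n = 3 each), a log2 fold change of 0.16 ± 0.065 SE (adjusted p = 0.0756). It was called without mevastatin replicate 2 (adjusted p = 0.0336) and without vehicle replicate 1 (0.0461). Of 11 tested receptors and ligands of the EGF family, 6 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.31 (camera, adjusted p = 0.0466; adjusted p = 0.509 with an estimated correlation). *HBEGF*, which encodes an EGF receptor ligand, rose 2.54-fold, from 52.9 ± 4.59 CPM to 134 ± 13.4 CPM (SD, n = 3 each; adjusted p = 8.99e-10). *TGFA*, another ligand of the receptor, rose 1.53-fold and *ERBB3* 1.41-fold, while *NRG1* fell 1.43-fold. The call of this list ended without mevastatin replicate 3 (adjusted p = 0.0933, median 0.20), vehicle replicate 2 (0.0786) or vehicle replicate 3 (0.0518).

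Immediate-early and feedback genes of ERK signalling were higher. Of 23 tested members, 15 were higher and 1 lower, also adjusted over the list alone, with a median log2 fold change of 0.62 (camera, adjusted p = 1.08e-05; adjusted p = 0.161 with an estimated correlation). *DUSP5*, a phosphatase that acts on ERK, rose 2.02-fold, *IER2* 1.93-fold and *PHLDA1* 1.54-fold. *CCND1*, the gene of cyclin D1, was the lower member and fell 1.35-fold. *MYC* rose 1.33-fold, from 176 ± 24.9 CPM to 234 ± 20.1 CPM (SD, n = 3 each; log2 fold change 0.41 ± 0.098 SE; adjusted p = 0.00921). The list of WNT and MYC targets was nevertheless lower, with 9 of 19 tested members lower and 3 higher (10 and 3 adjusted over the list alone; median log2 fold change -0.29; camera, adjusted p = 0.0185; adjusted p = 0.166 with an estimated correlation). In it *LGR5* fell 4.91-fold, *LGR4* fell 1.48-fold, and *ODC1*, a MYC target of polyamine synthesis, fell 1.47-fold. *DKK1*, a secreted WNT inhibitor, was higher by 1.94-fold, and the other higher members were *MYC* and *CTNNB1*, the latter named after its value was seen.

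**Figure D2:**
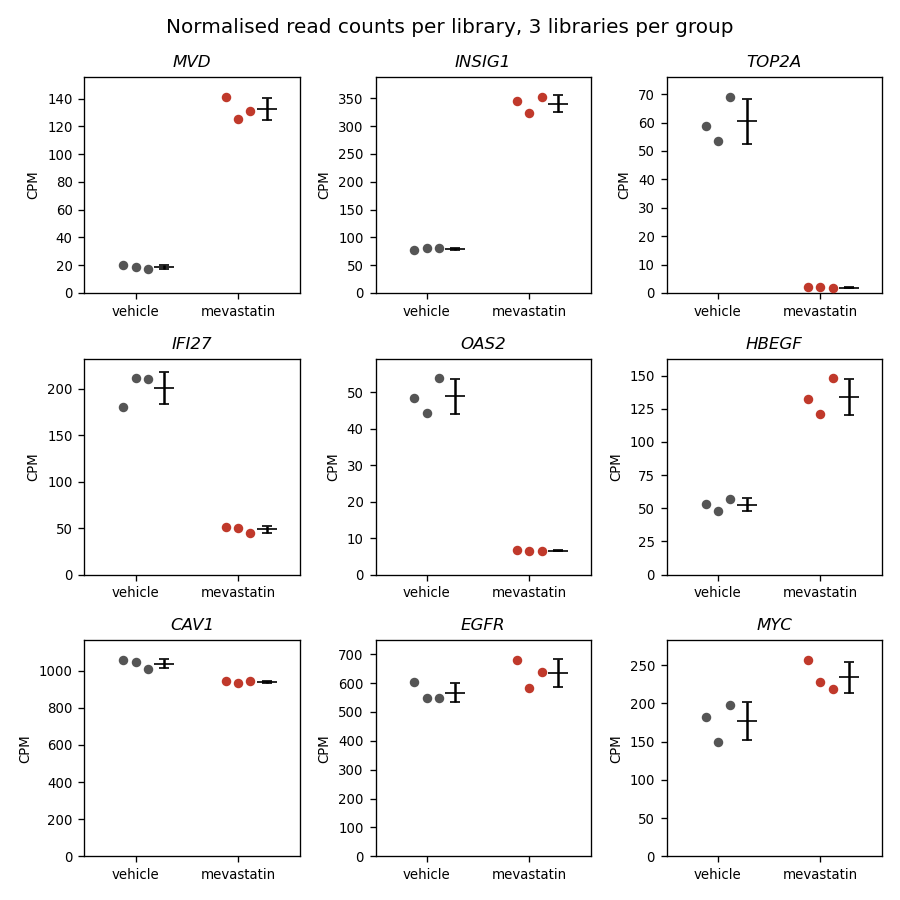
Normalised read counts (CPM, vertical axes from 0) of 9 genes in the 3 vehicle and 3 mevastatin libraries. Each point is a library, and the bar beside each group is its mean ± SD: *MVD*, *INSIG1* and *HBEGF* are higher and *TOP2A*, *IFI27* and *OAS2* lower in each mevastatin library than in each vehicle library, as *CAV1* is by less, while *EGFR* overlaps between groups.

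Markers of keratinocyte differentiation moved both ways, with more members higher. Of 47 tested, 16 were higher and 7 lower (22 and 7 adjusted over the list alone), with a median log2 fold change of 0.23 (camera, adjusted p = 0.00427; adjusted p = 0.414 with an estimated correlation). *GRHL3*, a transcription factor of barrier formation, rose 1.90-fold, and *KLK7*, a protease of the cornified layer, rose 1.53-fold. *LCE3D*, a late cornified envelope gene with close paralogs, rose 5.38-fold to 5.61 ± 0.929 CPM (SD, n = 3). *DSC1*, a desmosomal cadherin of upper layers, fell 1.44-fold. Basal-layer genes were not called as a list, with 6 of 17 higher and 7 lower (6 and 8 adjusted over the list alone, with a camera adjusted p of 0.865). Their median log2 fold change was -0.06 and their mean 0.01. *KRT15* rose 1.94-fold and *PLEC*, which anchors keratins at hemidesmosomes, 1.40-fold. *TP63*, a transcription factor of basal keratinocytes, fell 1.46-fold, from 956 ± 31.2 CPM to 654 ± 25.2 CPM (SD, n = 3 each), and *ITGA6* fell 1.28-fold. Barrier lipid genes were not called (9 higher and 4 lower of 20, 10 and 4 adjusted over the list alone, with a camera adjusted p of 0.180), with *ELOVL7* and *UGCG* 1.6-fold and 1.58-fold higher and *SPTLC3* and *DEGS1* 1.55-fold and 1.38-fold lower.

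Genes of activated, wound-edge keratinocytes were higher on balance, with 11 of 24 tested members higher and 4 lower, also adjusted over the list alone (median log2 fold change 0.23; camera, adjusted p = 0.0147; adjusted p = 0.394 with an estimated correlation). *PLAU*, the urokinase gene, rose 2.04-fold and *ITGA5*, a fibronectin receptor subunit, 1.80-fold. *FN1*, the fibronectin gene, fell 1.52-fold from 16433 ± 351 CPM (SD, n = 3), and *TNC*, the tenascin C gene, fell 2.97-fold. The other lower members, named after their values were seen, were *KRT6C* and *PTHLH*. The call of that list ended in fry (adjusted p = 0.0723). Antimicrobial peptide genes rose, with 6 of 9 higher and none lower (7 higher adjusted over the list alone; median log2 fold change 0.47; camera, adjusted p = 0.00116; adjusted p = 0.252 with an estimated correlation). *DEFB1*, a beta-defensin, rose 2.41-fold, *S100A7* 2.83-fold, *LCN2* 1.41-fold and *PI3* 1.38-fold. Of 23 tested inflammatory and NF-kB genes, 12 were higher and 3 lower, also adjusted over the list alone (median log2 fold change 0.50; camera, adjusted p = 0.00188; adjusted p = 0.403 with an estimated correlation). *LIF*, a cytokine of the interleukin 6 family, rose 4.13-fold to 7.49 ± 0.629 CPM (SD, n = 3), *IL1RN* 1.64-fold, *NFKB2* 1.59-fold and *IL1A* 1.54-fold. The lower members, named after their values were seen, were *IL24*, *IL33* and *IL20*. Without vehicle replicate 2 the median log2 fold change of that list was 0.26, and the list was still called.

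Oxidative stress targets of NRF2 were higher, with 15 of 23 higher and 1, *GSR*, lower (17 and 1 adjusted over the list alone; median log2 fold change 0.47; camera, adjusted p = 4.26e-06; adjusted p = 0.166 with an estimated correlation). *PGD*, an enzyme of the pentose phosphate pathway, rose 1.66-fold and *GCLC*, of glutathione synthesis, 1.54-fold. *AKR1C1* and *AKR1C2*, near-identical paralogs that can share reads, rose 1.91-fold and 1.65-fold. Targets of ATF4, a transcription factor of amino acid stress, were higher as a list, with 14 of 22 higher and 1, *SLC7A5*, lower, also adjusted over the list alone (median log2 fold change 0.27; camera, adjusted p = 0.000110; adjusted p = 0.414 with an estimated correlation). *TRIB3* rose 2.60-fold, *DDIT4*, which restrains mTORC1, 1.76-fold, *CEBPB* 1.66-fold and *NUPR1* 1.57-fold. Among 24 lysosome and autophagy genes, 10 were higher and 2 lower (11 and 2 adjusted over the list alone; median log2 fold change 0.16; camera, adjusted p = 0.0135; adjusted p = 0.254 with an estimated correlation). *SQSTM1*, the autophagy receptor p62, whose span overlaps *MGAT4B*, rose 1.85-fold and *CTSB*, a lysosomal protease, 1.41-fold. *NEU1* rose 1.59-fold and *WIPI1* 1.54-fold. *GSR* and *SLC7A5* were named after their values were seen.

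Chaperones of the endoplasmic reticulum were not called as a list (3 higher and 8 lower of 19, 3 and 9 adjusted over the list alone, with a camera adjusted p of 0.0686), with *PDIA4*, *CALR* and *HSP90B1* 1.51-fold, 1.46-fold and 1.40-fold lower and *EDEM1* 1.38-fold higher. It was called with no count filter (adjusted p = 0.0481), by fry (0.00910), without mevastatin replicate 1 (0.0475) and without vehicle replicate 3 (0.0413). Targets of p53 were not called either (8 higher and 3 lower of 23, 9 and 4 adjusted over the list alone, with a camera adjusted p of 0.186). The p53 list was called by fry (adjusted p = 0.000306). In that list *CDKN1A*, which encodes the cell cycle inhibitor p21, was 1.43-fold higher, *PLK3* 1.85-fold, *SESN2* 1.51-fold and *PHLDA3* 1.5-fold. Cytosolic heat shock genes (2 higher and 4 lower of 13, 2 and 5 adjusted over the list alone, with a camera adjusted p of 0.231) held *HSPA8*, 1.29-fold lower, and *DNAJB1*, 1.30-fold higher. Hypoxia and glycolysis genes (5 higher and 8 lower of 19, 6 and 8 adjusted over the list alone, with a camera adjusted p of 0.870) included *SLC2A3*, a glucose transporter, 3.42-fold higher, *ALDOC*, 2.08-fold higher, *NDRG1*, 1.67-fold higher, and *ADM*, 1.52-fold lower. The median and mean of that list were 0.01 and 0.06, while camera's direction was down.

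*NR3C1*, the glucocorticoid receptor gene, stood at 252 ± 7.40 CPM with vehicle and 261 ± 12 CPM with mevastatin (SD, n = 3 each; log2 fold change 0.05 ± 0.059 SE; adjusted p = 0.625). *GAS5*, a long noncoding RNA that binds this receptor, stood at 94.7 ± 2.37 CPM and 95.5 ± 12.3 CPM (SD, n = 3 each; log2 fold change 0.01 ± 0.079 SE; adjusted p = 0.927), with a span that overlaps *ZBTB37*. Their differences lay within the spread between replicates. Of 15 tested glucocorticoid targets, 6 were higher and 1 lower, also adjusted over the list alone (median log2 fold change 0.20; camera, adjusted p = 0.0470; adjusted p = 0.237 with an estimated correlation). *ANGPTL4*, whose span overlaps *RAB11B-AS1*, rose 1.82-fold, *TSC22D3*, which encodes the glucocorticoid-induced leucine zipper, 1.49-fold, *GLUL* 1.47-fold and *NFKBIA* 1.40-fold, and *SDPR* was the lower member. The call of this list ended without mevastatin replicate 3 (adjusted p = 0.0809), vehicle replicate 1 (0.0796) or vehicle replicate 2 (0.0751), and its median was 0.31 without mevastatin replicate 1 and 0.13 without mevastatin replicate 2. Kruppel-like factors were higher, with 6 of 13 higher and none lower (7 higher adjusted over the list alone; median log2 fold change 0.19; camera, adjusted p = 0.00298; adjusted p = 0.254 with an estimated correlation). *KLF6* rose 1.51-fold, *KLF7* 1.37-fold, *KLF3* 1.29-fold and *KLF13* 1.20-fold. In the list of cortisol synthesis, metabolism and receptor genes, 3 of 13 had enough counts to be tested. Of these, *HSD11B2*, whose span overlaps *AC009061.1*, and *NR3C1* were not called. *STAR* fell from 0.463 ± 0.162 CPM to 0.127 ± 0.0924 CPM (SD, n = 3 each; adjusted p = 0.0172). The call of *STAR* ended without mevastatin replicate 2 (adjusted p = 0.0917), mevastatin replicate 3 (0.0521), vehicle replicate 2 (0.12) or vehicle replicate 3 (0.0582). The log2 fold change of *STAR* was -1.91, or -2.66 without mevastatin replicate 1, and its span overlaps *ASH2L*.

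Prenylation enzymes, YAP and TAZ targets and actin genes showed no common direction. *RHOB* stood at 69.3 ± 2.89 CPM and 62.1 ± 6.06 CPM (SD, n = 3 each; log2 fold change -0.16 ± 0.075 SE; adjusted p = 0.133) and was called with library totals alone (adjusted p = 0.0464). Of 10 prenylation enzymes, *RCE1* was higher (1.33-fold; adjusted p = 0.0422) and *RABGGTB* lower (1.16-fold; adjusted p = 0.0287), and neither passed adjusted over the list alone (camera, adjusted p = 0.833). The call of *RCE1* ended in DESeq2 (adjusted p = 0.0502), with library totals alone (0.0706), with no count filter (0.0555) and without mevastatin replicate 1 (adjusted p = 0.0578), mevastatin replicate 2 (0.169), vehicle replicate 1 (0.0970) or vehicle replicate 3 (0.161), and that of *RABGGTB* ended without mevastatin replicate 1 (0.104), vehicle replicate 1 (0.0823) or vehicle replicate 2 (0.182). The spans of *RCE1* and *RABGGTB* overlap *C11orf80* and *ACADM*. YAP and TAZ targets (5 higher and 6 lower of 21, 6 and 6 adjusted over the list alone, with a camera adjusted p of 0.840) included *IGFBP3*, which fell 2.23-fold from 1061 ± 91.6 CPM (SD, n = 3), *RBMS3* and *CCDC80*, which were 1.5-fold and 1.33-fold lower, and *GADD45A*, 1.28-fold higher. Actin and serum response factor genes (6 higher and 3 lower of 17, 8 and 3 adjusted over the list alone, with a camera adjusted p of 0.532) included *ACTG1* and *VCL*, 1.39-fold and 1.32-fold higher, and *FILIP1L* and *TPM2*, 2.43-fold and 1.39-fold lower. The median of that list was 0.11, its mean -0.01 and camera's direction up. TGF-beta and mesenchymal-transition genes (5 higher and 6 lower of 23, also adjusted over the list alone, with a camera adjusted p of 0.840) included *BHLHE40* and *ID1*, 2.29-fold and 2.11-fold higher, *PMEPA1*, 1.35-fold higher, and *FN1*.

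The 12 largest increases held 4 genes of the lipid lists, *FADS2*, *MVD*, *ACSS2* and *ACAT2*. The top one was *KRT37*, a hair keratin gene, at 0.436 ± 0.146 CPM with vehicle and 5.70 ± 1.93 CPM with mevastatin (SD, n = 3 each; 12.5-fold; adjusted p = 5.06e-07), with a span that overlaps *AC003958.2*. *PRUNE2* rose 9.93-fold, *CEACAM1*, which encodes a cell adhesion molecule and overlaps *LIPE-AS1*, 7.20-fold, and *AGPAT9*, of glycerolipid synthesis, 6.49-fold. *PAPL* rose 5.99-fold, *LCE3D* 5.38-fold and *PLA2G3*, a secreted phospholipase gene, 5.04-fold. *RUSC1-AS1* rose 5.24-fold, but it lies within the span of *FDPS* and *RUSC1* and the strand setting of the counting is not given in the sources used here, so its reads cannot be told apart from theirs.

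Markers of other skin cell types differed in abundance. No leukocyte marker passed the count filter, and the most abundant one, *CD68*, stood at 0.155 CPM on average with vehicle. Of 10 tested fibroblast markers, 4 were lower and 1 higher, also adjusted over the list alone, and the list was not called (median log2 fold change -0.18, mean 0.03, camera's direction down; adjusted p = 0.577). Its median was 0.08 without vehicle replicate 1 and -0.28 without vehicle replicate 3. *SPARC* fell from 126 ± 7.93 CPM to 97.6 ± 5.23 CPM (SD, n = 3 each), *MMP2* was 1.32-fold and *FBN1* 1.85-fold lower, and *LUM* was higher at under 1 CPM. The other lower marker was *THY1*, named after its value was seen. Of 11 melanocyte markers, 3 were tested and none was called, with *MITF* at 6.49 ± 0.797 CPM and 6.25 ± 0.352 CPM (SD, n = 3 each). Of 10 endothelial markers, 2 were tested: *ERG*, whose span overlaps *SNRPGP13*, was 2.65-fold lower from 1.44 ± 0.430 CPM (SD, n = 3), and *VWF* had 3 counts over the vehicle libraries, all in vehicle replicate 2, and 61 over the mevastatin libraries, a ratio of 19 with a 95% exact interval of 6.20 to 94.6 for counting error only. Transcripts of the mitochondrial genome had 0 counts in each library and were not analysed here.

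The authors' deposited table also holds their own comparison by edgeR, DESeq and baySeq. Over 57275 genes, the authors' deposited table lists 4394 genes at an edgeR FDR under 0.05, 2147 higher and 2247 lower with mevastatin. The same table lists 3493 genes by DESeq and 1074 by baySeq at that threshold. Of the 4394 genes in the authors' deposited table, 4029 were also among the 4927 called here, each with the same sign. For *CAV1* the authors' deposited table gives a log2 fold change of -0.14 with an edgeR FDR of 0.319, and for *EGFR* 0.16 with an edgeR FDR of 0.351. Its DESeq adjusted p-values are 0.347 for *CAV1* and 0.262 for *EGFR*. The baySeq FDR is 0.117 for *CAV1* and 0.00909 for *EGFR*, so baySeq alone lists *EGFR* under 0.05.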

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

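The alternatives were chosen before the data were examined. The number of changed genes was 4922 with median-of-ratios scaling, 4798 in DESeq2, 5111 with library totals alone, 4924 with limma-voom, 4805 with a mean count of at least 50, 4992 with no count filter and 3873 to 4566 with one library left out, against 4927. No gene called both in edgeR with TMM and under one of these alternatives had the opposite sign. A 2-fold minimum left 826, by its own construction. Of the authors' genes, 2746 were shared at an adjusted p under 0.01 and 4029 at 0.05. Library totals alone moved the median of all tested genes by less than 0.1, to -0.05 on the log2 scale, while the split became 1996 higher and 3115 lower.

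The number of called lists moved most, among the alternatives run, with an estimated correlation. With an estimated correlation, camera called 0 of 34 lists (lowest adjusted p 0.0842), against 19 with the preset correlation of 0.01, and fry, which does not compare a list with other genes, called 23 (lowest adjusted p 3.89e-05). Of the 19, 18 were also called by fry, and the wound-edge list was not (adjusted p = 0.0723). For antigen presentation, WNT and MYC targets and glucocorticoid targets, the estimated correlations were -0.057, -0.028 and -0.0014. These lie below the preset 0.01, and the calls of these lists ended as well. A correlation above the preset value is thus argued against as the reason for these lists. The other called lists had estimated correlations between 0.045 (lysosome and autophagy) and 0.53 (targets of ATF4). In the simulated counts, whose genes were independent, camera's adjusted p for the raised list also went from 7.99e-34 to 0.0168 with an estimated correlation. Larger p-values with this setting therefore did not require correlated genes there. What ended the calls was not tested further. Among the lists reported here that were not called by camera, fry called histones (0.0286) and chaperones of the endoplasmic reticulum (0.00910). It also called targets of p53 (0.000306) and of the liver X receptors (0.00185). The number of lists was 19 with both other scalings and with a mean count of at least 50, 21 with no count filter and 17 to 20 with one library left out.

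The replicate number was tested as a block, although the replicate numbers did not pair the libraries: the correlations of residuals across genes between libraries of the same number were -0.0035, 0.038 and 0.041, and those of different numbers lay between -0.070 and 0.039. Genes are not independent replicates. With the block, 4832 genes and 18 lists were called, and the calls of EGF family genes (adjusted p = 0.0502) and of glucocorticoid targets (0.0781) ended. The histone list was called (0.0289), and *SDPR* was not (0.0902). Not every library correlated best with its own number. The cause was not tested.

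The results that changed sign did not pass the threshold before or after. With library totals alone, the log2 fold change was -0.033 for *GAS5*, -7.92e-05 for *NR3C1* and -0.010 for *PMEL*, and with the block it was -0.0027 for *PMEL*. In fry the direction was opposite to camera's for basal keratinocyte genes (median -0.056), hypoxia and glycolysis (0.0051) and YAP targets (0.095), for which the medians stayed as they were. With one library left out, the log2 fold change ranged from -0.073 to 0.11 for *GAS5*, from -0.12 to 0.054 for *MITF* and from -0.18 to 0.25 for *PMEL*. List medians ranged from -0.28 to 0.085 for fibroblast markers, from -0.028 to 0.036 for hypoxia and glycolysis and from -0.0089 to 0.092 for prenylation enzymes. For TGF-beta and mesenchymal-transition genes (-0.12 to -0.017) and YAP targets (0.012 to 0.11) the medians kept their sign, and camera's direction changed without 1 library. The cause was not tested.

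Of 164 named genes, 162 kept direction and side of the threshold in DESeq2 and 163 with limma-voom. With library totals alone 158 did. Alternatives for normalised values alone were not run, since counts were deposited. Depth limits the size of change of genes with few counts, as with *HIST1H3G* (2 counts with mevastatin).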

Other observations

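The count of splits for changed genes, the tests of scaling, fibroblast markers, leukocyte markers, *IFNK* and pseudogenes, and the gene families were chosen after the result was seen, while leaving out each library was set before the data were examined.

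The real split of the 6 libraries gave 4927 changed genes, and the highest of the other splits gave 0 in edgeR (up to 440 genes at an unadjusted p under 0.05). In 1 of 10 splits, the real one, the number was as large. For gene lists the real split gave 19 and the highest other split 15, again with 1 of 10 as large. Each other split put libraries of both treatments on each side, so the treatment difference added to the spread within sides. The 0 changed genes there can follow from that alone and do not test whether the 4927 arose by chance. The other splits still called 5 to 15 lists by camera with 0 changed genes. Their sides held unequal numbers of mevastatin libraries, so these calls do not measure false calls. With 10 splits, a share under 0.05 cannot be reached.

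Cell-cycle genes fell by a median of -3.66 (log2) for the mitosis list. The lower quartile of the tested genes outside this list was -0.21, while the upper quartile of the list was -2.79. TMM scaling assumes that most genes change little (median log2 fold change of all tested genes -0.0015). The first value alone could therefore not have shown a shared shift. Scaling of the libraries moves all genes of a library alike and leaves the gap between the list and other genes unchanged. It is argued against for that gap only. Fibroblast markers had a lower quartile of -0.39, with 4 of 10 tested markers lower and 1 higher. This argues against a loss of dividing fibroblasts only if fibroblasts supplied these transcripts. Which cells supplied them was not tested. Fewer dividing keratinocytes with mevastatin may account for the fall, which remains a hypothesis, since no measurement of division was used here.

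Interferon-stimulated genes fell by a median of -1.45 (log2). Leukocytes in the vehicle cultures are argued against, since the most abundant leukocyte marker stood at 0.155 CPM with vehicle while *IFI27*, an interferon-stimulated gene, stood at 201 CPM. One vehicle library with a high response is argued against, since with any one library left out the median stayed between -1.73 and -1.40. A candidate explanation is *IFNK*, which encodes an interferon that keratinocytes make. It fell 2.18-fold, from 229 ± 32.1 CPM to 105 ± 9.31 CPM (SD, n = 3 each), lower in 3 of 3 libraries. Its log2 fold change was -1.13 (adjusted p = 2.49e-06 in edgeR). *IFNE*, another interferon gene that was tested, did not fall, at 5.63 ± 0.490 CPM with vehicle and 6.23 ± 0.684 CPM with mevastatin (SD, n = 3 each). The log2 fold change of *IFNE* was 0.15 (adjusted p = 0.466 in edgeR). Other causes stay open.

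Most pseudogenes of changed parent genes moved with them. Over 24 pairs from 15 parents that changed at least 2-fold, the pseudogene's log2 fold change was a median 0.857 of its parent's (quartiles 0.782 and 1.01), with the same sign in 22 pairs, while *DUSP5P1* (-0.61, parent 1.01) and *KRT19P3* (-0.05, parent 2.04, at 82.9 CPM against its parent's 1.74 CPM) did not follow. Across these pairs r was 0.940 and rho 0.902 (permutation p = 1e-04, the smallest that 10000 permutations can give), and across all 1444 pairs r was 0.691 and rho 0.481, though pairs that share a parent are not independent. Reads shared between a pseudogene and its parent may therefore account for the changes of the 19 pseudogenes that were called with their parent's sign. Whether that holds for the 374 pseudogenes called in all was not tested, and transcription of the pseudogenes themselves stays open.

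Gene families, some of whose members are also in the lists, were tested with camera and adjusted over the 8 families. Because the families were chosen after the values were seen, their p-values are descriptive and give no independent support. Of 28 keratin genes, 12 were higher and 3 lower (adjusted p = 0.00149; adjusted p = 0.116 with an estimated correlation), or 10 and 3 with library totals alone. *KRT34* rose 4.64-fold, from 66.4 ± 1.1 CPM to 308 ± 48.6 CPM (SD, n = 3 each). The keratin genes *KRT14*, *KRT5*, *KRT1* and *KRT10* were not called in edgeR with TMM. Their log2 fold changes were 0.01, -0.06, -0.10 and 0.18 (adjusted p = 0.927, 0.530, 0.681 and 0.0527). With median-of-ratios scaling *KRT10* was called (adjusted p = 0.0496). Of 47 genes of the first histone cluster, 36 were lower and none higher (adjusted p = 1.60e-17; adjusted p = 0.116 with an estimated correlation). Of 12 PARP genes, 7 were lower and 1 higher (adjusted p = 0.00149; adjusted p = 0.0910 with an estimated correlation). Of 10 genes of the origin recognition and GINS complexes, 8 were lower and none higher (adjusted p = 9.14e-06; adjusted p = 0.0627 with an estimated correlation). Of 24 collagen genes, 12 were lower and 3 higher (adjusted p = 0.0466; adjusted p = 0.320 with an estimated correlation). Integrins (adjusted p = 0.948), inhibitors of cyclin-dependent kinases (0.218) and glucose transporters (0.948) were not called.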
